A study of Mus musculus with 10 samples.

How the data were processed

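Polyadenylated RNA from whole liver of female mice was sequenced. The mice either carried a floxed glucocorticoid receptor gene together with LysM-Cre, which is active in macrophages and other myeloid cells (GRMAC), or the floxed gene without Cre (GRflox, littermate controls). The livers were taken after a fast of 8 h that began at ZT12, the onset of the active phase, per the labels. Each group had 5 libraries. The labels number the libraries within each genotype but do not state that each is a different animal; each was treated as 1 animal. RNA was prepared for paired-end sequencing with an NEBNext Ultra kit, per the labels' protocols.

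The authors deposited one table of read counts per gene, with whole numbers in 10 columns, and 1 RefSeq transcript and 1 symbol per row. The submitters' processing notes name HISAT2 2.1.0, DESeq2 1.24.0 and the genome build mm10. The counting program, the annotation version, the strand setting and whether introns were counted are not stated. Hspa1b, a gene without introns, had 53.3 CPM in GRflox liver, so the values are not of introns alone. The control and knockout columns of the table were matched to the sample titles by genotype and number. A second deposited table holds log2 fold changes of knockout against control, per the file headers. The same table gives the authors' adjusted p-values, per the file headers, left empty where none was given. Its design formula is not stated. It also holds 10 columns of values per library that were not used here. Coordinates are those of the count table, printed with the first base counted as 1.

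The table has 19764 genes, and the libraries held 23258884 to 27692528 counts. A count of 3 in a library corresponds to 0.108 to 0.129 CPM. Genes with too few counts were removed with filterByExpr of edgeR 4.0.16, which left 12558 genes and took away 0.0348% of the counts. Libraries were scaled by TMM. GRMAC was compared with GRflox by edgeR's quasi-likelihood test with robust estimation (R 4.3.3), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM values are scaled by TMM and given as means ± SD. Single values per library were compared with a two-sided exact permutation test over the 252 assignments of 5 against 5, whose smallest p is 0.00794.

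Before the data were examined, 28 gene lists were fixed (metabolic pathways, stress and immune responses, and markers of liver cell types), as were the genes to be named. These were 10 genes given whatever their result; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean CPM of at least 1, or all of them where fewer passed; and from each list up to 4 members past the threshold, or else the member with the lowest p. Some genes that this rule takes are not used here. Genes named outside that rule are members of the fixed lists that passed the threshold adjusted over the list alone, or are said to have been chosen after their values were seen. Lists with at least 3 measured members (26 lists) were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the lists. A list score is the mean over members of log2 CPM centred per gene. The alternatives were camera with an estimated correlation, fry, and an exact permutation test of the list scores.

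The scripts were tested on simulated data for this comparison, with counts drawn for the 12558 genes and 200 of them changed. The edgeR test recovered 70.1% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 3.95% false calls. DESeq2 1.42.0 recovered 77.6%, 88.1% and 97.0% at the same folds, with 9.33% false calls, and limma-voom 70.1%, 91.0% and 97.0%, with 2.82% false calls. These rates hold for 200 changed genes drawn independently, so they do not give the share found in the real data. Other alternatives were DESeq2, limma-voom with and without sample weights, edgeR without robust estimation, other scalings and filters, the replicate number as a block, and leaving out each library in turn. After the data were seen, a correction for GC content and exonic length was added (splines with 5 degrees of freedom per library; 99.7% of tested genes had both values, from GENCODE transcripts), as were thinning of every library to the smallest total and a fit without GRflox 4 and GRMAC 4.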

Results

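Liver RNA was compared between 5 GRMAC libraries, from female mice whose macrophages and other myeloid cells were made to lose the glucocorticoid receptor, and 5 libraries from GRflox littermates, all fasted for 8 h from ZT12. Library totals ranged from 25697931 to 27692528 counts in GRflox and from 23258884 to 26116916 in GRMAC (n = 5 each), and they differed between the genotypes (exact permutation test, p = 0.0159). The comparison asks which liver transcripts differ in fasted mice when macrophages and other myeloid cells are made to lose the receptor. The controls lacked Cre, so an effect of LysM-Cre itself cannot be told apart from loss of the receptor. No fed mice were included. The first principal component, with 21.5% of the variance, separated the genotypes (exact permutation test, p = 0.00794, the smallest possible).

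Nr3c1, which encodes the glucocorticoid receptor (NM_008173, mm10 chromosome 18, 39410545 to 39487245), was at 72.8 ± 7.14 CPM in GRflox and 82.5 ± 7.75 CPM in GRMAC liver (SD, n = 5), a difference that did not pass the test (log2 fold change 0.18 ± 0.08 SE, adjusted p = 0.277 with edgeR). The libraries ranged from 63.8 to 81.2 CPM in GRflox and from 74.7 to 94.0 CPM in GRMAC. One count per gene cannot show a deleted exon, and most liver RNA comes from cells without LysM-Cre, so this level does not check the deletion. Lyz2, the gene that carries the Cre insertion of LysM-Cre (chromosome 10, 117277541 to 117282272), was at 32.3 ± 5.51 CPM in GRflox and 21.1 ± 5.21 CPM in GRMAC. Its log2 fold change of −0.62 ± 0.16 did not pass with edgeR (adjusted p = 0.114) and passed with DESeq2 (adjusted p = 0.00904); the exact permutation test gave p = 0.0317.

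Cd163, the haemoglobin scavenger receptor of resident macrophages (NM_053094, chromosome 6, 124304651 to 124330527), fell from 28.8 ± 7.81 CPM in GRflox to 3.07 ± 0.493 CPM in GRMAC liver (SD, n = 5), a log2 fold change of −3.22 ± 0.19 (adjusted p = 2.55e-05, edgeR). Pla2g7, which encodes platelet-activating factor acetylhydrolase (NM_013737, chromosome 17, 43568451 to 43612201), fell from 3.75 ± 0.578 to 0.809 ± 0.270 CPM (−2.20 ± 0.21, adjusted p = 0.000457, edgeR). Both genes were lower in every GRMAC library than in any GRflox library. The other 20 genes past the edgeR threshold had absolute log2 fold changes from 0.32 to 0.86.

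**Figure D1:**
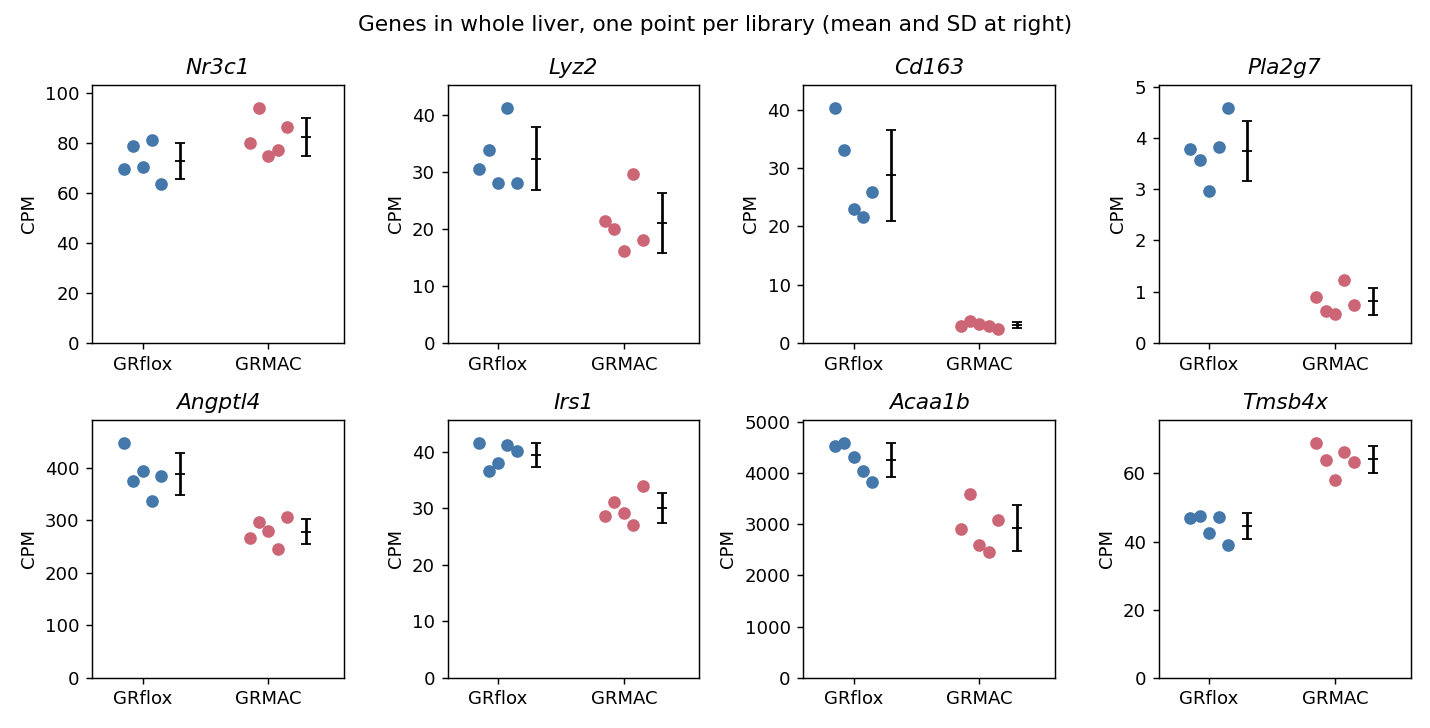
CPM of 8 genes (y axis, from 0) in the 5 GRflox and 5 GRMAC libraries, 1 point per library, with the mean and SD to the right of each group. Cd163 and Pla2g7 lie far lower in all GRMAC libraries, whereas the ranges of Nr3c1 and Lyz2 overlap between the genotypes.

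Among the other genes that fell were Angptl4, an inhibitor of lipoprotein lipase and a PPARA target (387 ± 40.0 to 278 ± 24.2 CPM, log2 fold change −0.48 ± 0.08), and Irs1, an adaptor of the insulin receptor (39.5 ± 2.15 to 30.0 ± 2.64 CPM, −0.40 ± 0.07). Nfe2l1, a transcription factor of proteasome genes, fell by 0.35 on the log2 scale (215.9 ± 11.9 to 169.8 ± 8.92 CPM). Dnmbp (−0.48) and Tmem189 (−0.37) fell as well. The 10 largest rises were those of Gprin3 (0.86 ± 0.13), Zyg11a (0.70), Olfr1033 (0.70 ± 0.08), the corepressor gene Rcor3 (0.68), Zfp945 (0.58), Tmsb4x, which encodes thymosin beta-4 (44.6 ± 3.76 to 64.1 ± 4.05 CPM, 0.52 ± 0.07), the ribosomal protein gene Rpl39 (0.50), the DNA damage kinase gene Atm (0.49), the coagulation factor gene F11 (0.47) and the syndecan gene Sdc3 (0.46). Olfr1033 belongs to a large gene family, and Rpl39 and Tmsb4x have many processed copies, so their counts are uncertain.

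In all, 22 of 12558 genes passed with edgeR (15 higher and 7 lower in GRMAC). None of the 22 overlapped between the genotypes; 509 of all tested genes (4.05%) did not, where chance gives 0.794%. At an unadjusted p under 0.05 there were 2051 genes, with 628 expected by chance. The count depended on the tool: DESeq2 refitted to the same counts called 425 genes (234 higher, 191 lower) and limma-voom called 8. It was 9 after a correction for GC content and exonic length chosen after the data were seen, and 5 to 47 when a library was left out. Of the 14 calls lost with that correction (adjusted p from 0.0643 to 0.144), 9 had fold changes that moved by less than their standard error, such as Angptl4 (−0.48 before and after) and Rpl39 (0.50 and 0.52). The other 5, named after their values were seen, had smaller rises: Atm (0.49 and 0.38), Zfp945 (0.58 and 0.42), Map3k2 (0.43 and 0.28), Rev3l (0.41 and 0.29) and Atrx (0.32 and 0.17).

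The authors' deposited comparison held 424 genes at adjusted p under 0.05 (234 higher and 190 lower in the knockout). All 22 edgeR calls were among them in the same direction, as were 424 of the 425 calls of the DESeq2 refit. Each of the 424 had an unadjusted edgeR p under 0.05 and the same sign.

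PPARA target genes, which serve the use of fatty acids in the fasted liver, were lower in GRMAC liver as a group by camera with the preset correlation (adjusted p = 6.27e-14). The call was lost with an estimated correlation (p = 0.0548, adjusted p = 0.289). Other splits of the 10 libraries passed a median of 7 lists with the preset correlation, so passing it is weak evidence. All 34 measured PPARA targets had a negative log2 fold change (median −0.25), and 16 fell when adjusted over the list alone. Over all genes tested 1 (Angptl4) fell with edgeR, and 8 were lower in the authors' deposited DESeq2 comparison. Acaa1b, a peroxisomal thiolase gene, went from 4258 ± 328 to 2930 ± 449 CPM (−0.54 ± 0.10), and Cyp4a14 from 10160 ± 954 to 7938 ± 1220 CPM (−0.36 ± 0.11). Both passed over the list alone but not over all genes with edgeR (adjusted p = 0.0543 for Acaa1b and adjusted p = 0.145 for Cyp4a14). List scores overlapped: GRflox 4 (−0.108) lay among the GRMAC libraries and GRMAC 4 (0.072) above it (exact permutation test, p = 0.0238, adjusted p = 0.0884). Without both libraries, left out after the data were seen, the median was −0.38. These 2 libraries lie against their genotype on this score, so leaving them out favours a larger fall and adds no evidence.

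The 26 enzymes of fatty acid oxidation and ketogenesis had a smaller median of −0.13, with 20 negative and none passing over the list alone with edgeR. In the authors' deposited comparison 4 of them passed over all genes, all lower. Slc25a20, the carnitine-acylcarnitine carrier gene, had the lowest p (285 ± 10.8 and 249.8 ± 4.48 CPM, −0.19 ± 0.05), and Cpt1a, the rate-limiting enzyme of mitochondrial fatty acid import, was at −0.10 ± 0.10. The list passed camera with the preset correlation (adjusted p = 0.000123), and had adjusted p = 0.289 with an estimated correlation. Of its members 8 are also in the PPARA list. Fgf21, a hepatokine of fasting, was at 24.3 ± 3.98 and 15.9 ± 7.65 CPM (−0.61 ± 0.31, adjusted p = 0.363, edgeR).

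Of the 16 heat shock genes, 12 fell when adjusted over the list alone and none over all genes with edgeR (median −0.48). In the authors' deposited DESeq2 comparison 7 were lower over all genes. Hspa1b was at 53.3 ± 30.5 CPM in GRflox and 14.9 ± 1.96 CPM in GRMAC (−1.84 ± 0.39), Hspb1 at 95.5 ± 40.6 and 48.9 ± 11.6 CPM (−0.97), and Hsp90aa1 at 389 ± 147 and 236 ± 25.7 CPM (−0.72). Hspa1a and Hspa1b are nearly identical, so their counts are uncertain. Scores of this list spread more in GRflox (SD 0.364) than in GRMAC (SD 0.091). Camera gave adjusted p = 1.12e-07 with the preset and adjusted p = 0.33 with an estimated correlation. The exact permutation test of the list scores gave p = 0.00794 (adjusted p = 0.0825).

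Glucocorticoid-induced genes (25 measured) had a median of −0.28, and 20 were negative. Tat, which encodes tyrosine aminotransferase, fell when adjusted over the list alone (3177 ± 652 to 1716 ± 715 CPM, −0.89 ± 0.26), whereas the metallothionein genes Mt1 (0.68 ± 0.17) and Mt2 (156.8 ± 34.7 to 279.5 ± 51.1 CPM, 0.83 ± 0.17) rose. Metallothioneins also respond to metals and inflammation. Fkbp5 (−0.14 ± 0.29), Per1 (−0.39 ± 0.22) and Tsc22d3 (−0.41 ± 0.23) did not pass. Genes of gluconeogenesis and amino acid catabolism (31) had a median of −0.19, and only Hgd, of tyrosine breakdown, fell over the list alone (632.9 ± 44.6 to 513.7 ± 3.54 CPM, −0.30 ± 0.06). Camera gave adjusted p = 0.00535 for the first list and adjusted p = 0.000203 for the second with the preset correlation, and adjusted p = 0.289 for both with an estimated correlation. An exact permutation test of the list scores gave p = 0.00794 for the first and p = 0.0159 for the second (adjusted p = 0.0825 for both). The median of the glucocorticoid list was −0.42 with limma-voom.

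Acute phase genes (31) had a median of 0.21, and of 0.13 without GRMAC 2, the library with the highest score of this list (0.333). Adjusted over the list alone 7 rose and none fell, among them the fibrinogen genes Fga (3570 ± 254 to 4908 ± 622 CPM, 0.46 ± 0.09), Fgb (0.37) and Fgg (0.40), and Apcs (0.46), which encodes serum amyloid P. Of 16 antigen presentation genes 10 rose over the list alone (median 0.32), among them H2-Aa (11.4 ± 2.65 to 16.1 ± 1.41 CPM, 0.49 ± 0.14), H2-Ab1 (0.56), Cd74 (0.44) and their activator Ciita (0.48). Cholesterol synthesis genes (24) had a median of 0.23, with 21 positive, and Stard4, a sterol carrier gene, rose over the list alone (0.47 ± 0.11). Interferon response genes (38) had a median of 0.14, and Irf7 (0.35) and Oasl2 (0.60) rose over the list alone. No member of these 4 lists passed over all genes tested with edgeR. In the authors' deposited comparison 7, 2, 1 and 3 members passed as higher, and none as lower. Camera with the preset correlation passed all 4 lists (adjusted p = 0.000244, 1.85e-06, 6.89e-05 and 0.00193). With an estimated correlation the adjusted p were 0.423, 0.289, 0.289 and 0.438.

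**Figure D2:**
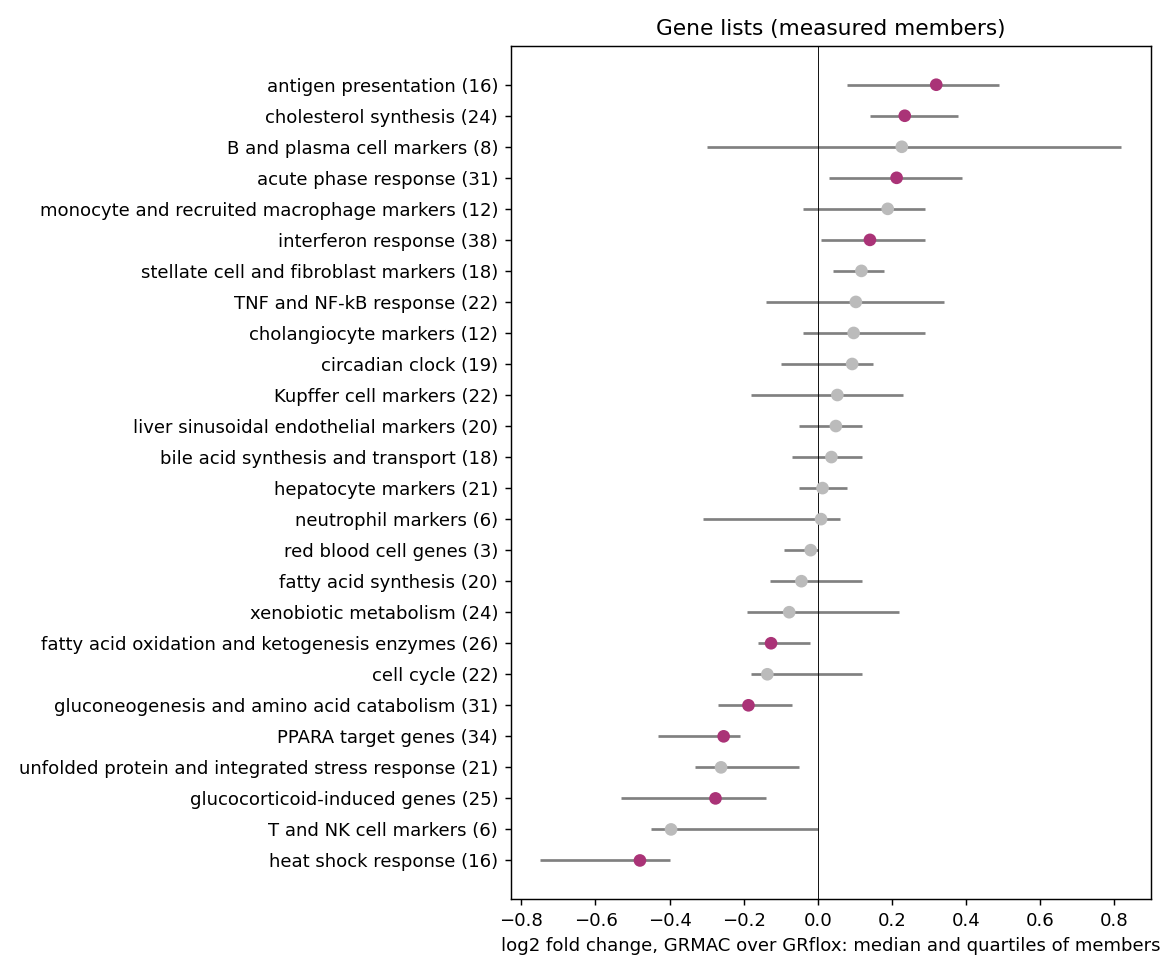
Median (point) and quartiles (line) of the log2 fold changes of GRMAC over GRflox (x axis) for the members of the 26 tested gene lists (y axis, measured members in brackets). Purple points mark the 9 lists that passed camera with the preset correlation, 4 higher and 5 lower in GRMAC; with an estimated correlation 0 passed.

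Kupffer cell markers, of the resident liver macrophages, moved apart. Of 22 measured, Cd163 and Cd207 (4.46 ± 1.78 to 1.18 ± 0.546 CPM, −1.91 ± 0.34) fell over the list alone, and Cd5l (46.2 ± 7.27 to 67.9 ± 12.5 CPM, 0.55 ± 0.13), Cybb (0.36), Folr2 (0.41) and Cd68 (0.42) rose. The median was 0.05 and the mean −0.18, and the list test was positive and did not pass (camera, adjusted p = 0.777). Hepatocyte markers (21) had a median of 0.01. B and plasma cell markers (8 measured) had a median of 0.23, and Cd79b (0.445 ± 0.0983 to 0.848 ± 0.204 CPM) and Cd22 (0.825 ± 0.225 to 1.44 ± 0.373 CPM) rose over the list alone, both at low levels.

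**Figure D3:**
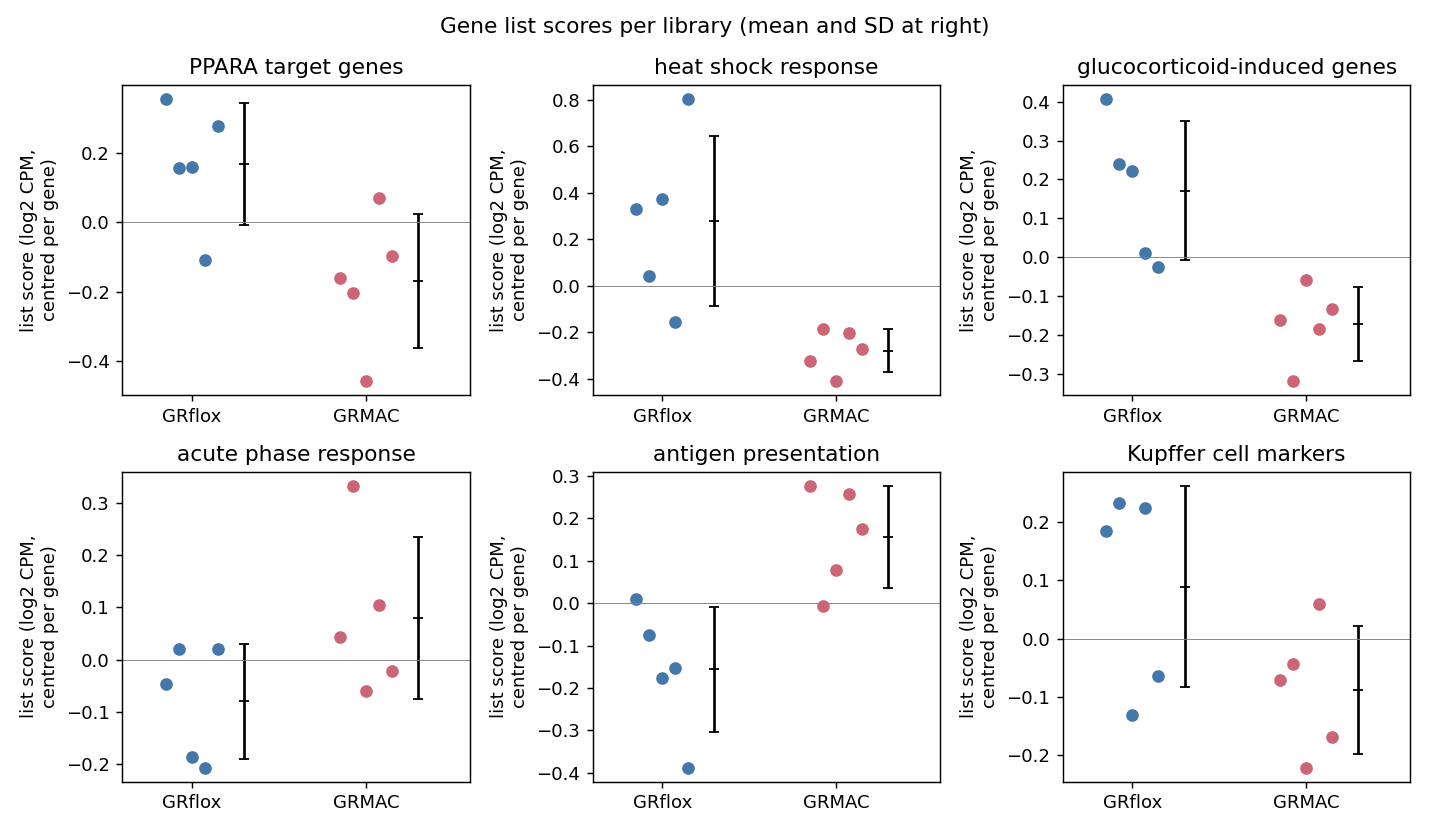
Scores of 6 gene lists (y axis, mean of log2 CPM centred per gene) in the 5 GRflox and 5 GRMAC libraries, with the mean and SD to the right of each group. PPARA target scores overlap between the genotypes, with GRflox 4 at −0.108 and GRMAC 4 at 0.072, and heat shock scores spread widely in GRflox.

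Other cell type lists did not pass camera with all 10 libraries. Medians were 0.19 for monocyte and recruited macrophage markers (12 measured), 0.01 for neutrophil markers (6, with a mean of −0.10), −0.40 for T and NK cell markers (6), 0.05 for sinusoidal endothelial markers (20), 0.12 for stellate cell and fibroblast markers (18), 0.10 for cholangiocyte markers (12) and −0.02 for red blood cell genes (3). Some of these lists passed, as higher in GRMAC, when 1 library was left out: sinusoidal endothelial markers without GRMAC 2 (adjusted p = 0.00027), stellate cell and fibroblast markers without GRMAC 2 (adjusted p = 0.000891) or GRflox 2 (adjusted p = 0.0234), and monocyte markers without GRflox 5 (adjusted p = 0.0168). Of the genes with the lowest p in these lists, Ccr2 was at 0.62 ± 0.21, Fpr1 at −0.48, Cd247 at −0.52, Stab2 at 0.23, Colec11 at 0.20 and Krt23 at −1.20 ± 0.36. Pancreas and adipose genes (2 measured) and mitochondrially encoded transcripts (0 in the table) were not tested.

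TNF and NF-kB response genes (22 measured) had a median of 0.10; Rel rose (0.71 ± 0.16) and Vcam1, an endothelial adhesion molecule gene, fell (16.1 ± 3.7 to 9.71 ± 1.53 CPM, −0.73 ± 0.15) over the list alone. Tnf lay below the filter, with 0 to 10 counts per library, and Il1b was at 2.52 ± 1.39 and 4.53 ± 3.73 CPM (0.84 ± 0.68). Among 24 xenobiotic metabolism genes (median −0.08) Cyp2b9 (0.48) and Cyp3a13 (0.26) rose and Gstp1 (−0.49 ± 0.09) fell over the list alone. Medians were −0.04 for fatty acid synthesis (20, with a mean of 0.01; Fads2 −0.18), 0.04 for bile acid synthesis and transport (18; Abcb4 −0.22), 0.09 for circadian clock genes (19; Wee1 rose over the list alone, 0.51), −0.14 for cell cycle genes (22; Birc5 0.58) and −0.26 for the unfolded protein and integrated stress response (21; Chac1 0.90). None of these lists passed camera in the main test, with all 10 libraries and no block. The stress response list passed, as lower in GRMAC, without GRflox 4 (adjusted p = 0.00526) or GRMAC 2 (adjusted p = 0.0144), and without GRflox 4 and GRMAC 4 together (adjusted p = 0.0416). With all 10 libraries it passed when the replicate number was a block, as given below.

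Across genes, fold changes fell with GC content (Spearman's rho −0.22, across genes, which are not independent replicates). The median log2 fold change was 0.08 in the tenth of genes with the lowest GC content and −0.05 in the tenth with the highest. The genes that rose had a median GC content of 43.5%, against 50.7% for those that fell and 50.5% for all tested genes.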

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

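The GC and depth tests in this part were set before their results were seen. Of 156 groups of 5 values examined for 1 value far from the other 4, 10 were picked out, where chance gives about 8 (1 in 20). Per1 was at 66.6 CPM in GRflox 4, against 83.1 to 90.8 in the other GRflox libraries, and at 31.0 CPM in GRMAC 4, against 63.4 to 78.6 in the other GRMAC libraries. In GRMAC 4 Tmem189 was at 19.5 CPM, above 16.2 to 17.1 in the others. In GRflox 3 Rcor3 was at 9.09 CPM (others 12.6 to 13.9), Fpr1 at 1.52 CPM (others 2.48 to 2.74) and the circadian clock score at −0.237 (others 0.0113 to 0.0557). Zyg11a was at 8.20 CPM in GRflox 5 (others 10.8 to 12.1). The sinusoidal endothelial score of GRMAC 2 was −0.466 (others 0.0179 to 0.215), and the stellate cell score of GRflox 2 was 0.173 (others −0.146 to −0.0639).

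The slope of log2 expression on GC content, per 10 points of GC, was 0.00928 in GRMAC 5, against −0.0542 to −0.0427 in the other GRMAC libraries. Mean slopes were 0.035 ± 0.027 in GRflox and −0.035 ± 0.025 in GRMAC (SD, n = 5), and they differed (exact permutation test, p = 0.0159), though GRMAC 5 lay just above GRflox 1 (0.008). A bias of single libraries unrelated to genotype cannot be told apart from a genotype effect, since the groups differ and yet overlap in that library. After thinning to the smallest total rho stayed at −0.223. Thinning takes from all genes of a library alike, so it cannot decide whether what lowered the GRMAC totals also made the trend. No batch is given in the labels, and a genotype effect on AT-rich transcripts stays open.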

How the results depend on the processing

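The corrections for GC content and exonic length, the thinning and the fit without GRflox 4 and GRMAC 4 were chosen after the data were seen. The 22 genes became 425 with DESeq2 (all 22 shared), 8 with limma-voom, 8 with edgeR without robust estimation (7 shared each), 34 without a filter, 9 with the GC and length correction (8 shared), 68 without GRflox 4 and GRMAC 4 (16 shared), 6 with a fold of at least 1.5 and 241 at adjusted p under 0.1. Leaving out 1 library gave 5 to 47 genes: 9, 6, 5, 26 and 5 without GRflox 1 to 5, and 10, 16, 14, 10 and 47 without GRMAC 1 to 5; the cause was not tested. The self-test had 9.33% false calls with DESeq2 and 3.95% with edgeR. It drew genes independently, with a spread estimated by edgeR, so it does not decide between the tools for these data. Same-numbered libraries deviated together only in part, which leaves pairing unresolved. Of 5 correlations 2 were over 0.1 (0.17 for number 2 and 0.15 for number 3), and number 4 had −0.11. In each genotype 2 libraries correlated best with their own number. With the replicate number as a block there were 81 genes, 20 of them shared, and the unfolded protein and integrated stress response list passed camera (adjusted p = 0.0219). Lyz2 passed with DESeq2 (−0.62), the replicate block (−0.63) and without both libraries (−0.67), with adjusted p from 0.00579 to 0.197 over its 23 alternatives. Nr3c1 stayed between 0.08 and 0.25 and never passed. The 9 gene lists became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation test (7 at unadjusted p under 0.05) and 0 with the GC correction and an estimated correlation together; 2 had an unadjusted p under 0.05 with an estimated correlation. Shared calls with the authors' table went from 22 to 241 at adjusted p under 0.1 in both and to 424 with DESeq2. Cd163 and Pla2g7 passed under all 23 alternatives. Angptl4 lost its call under 11, Irs1 under 12 and Nfe2l1 under 10. No named gene or list past the threshold changed direction. Of results for named genes 963 kept their side of the threshold, 153 lost it and 30 gained it; of those for lists 500, 36 and 8. Counts of introns in place of whole genes could not be run, since the table holds one count per gene. At 3 counts per library, Tnf and other low genes cannot be compared.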

Other observations

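Tests on Kupffer cells and hepatocytes, the proteasome and ribosomal protein lists, the exchange of libraries, and the 6 genes of this paragraph were chosen after results were seen. Outside the fixed lists, 18 genes had an edgeR adjusted p from 0.05 to 0.1 and at least a doubling or halving, 12 higher and 6 lower in GRMAC; 6 of the 18 are given here, and no enrichment was tested. Hpgds, a prostaglandin D synthase gene, was at 1.04 CPM in GRflox and 2.37 CPM in GRMAC (log2 fold change 1.18 ± 0.22, adjusted p = 0.0543), and Aif1, a macrophage gene, had a log2 fold change of 1.05 ± 0.20 (adjusted p = 0.0543). Lower in GRMAC were the endothelial lipase gene Lipg (71.1 and 26.5 CPM, −1.43 ± 0.25, adjusted p = 0.0628), the B cell chemokine gene Cxcl13 (4.03 and 0.977 CPM, −2.04 ± 0.41, adjusted p = 0.0649), Adam22 (6.21 and 2.33 CPM, −1.42 ± 0.27), and Mefv (0.969 and 0.418 CPM, −1.20 ± 0.24). None of these passed 0.05 with edgeR, and all 6 passed in the authors' DESeq2 table (adjusted p from 2.88e-05 to 0.0083), as did 17 of the 18.

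Cd163 and Pla2g7 fell 9.34-fold and 4.61-fold. Fewer Kupffer cells would lower the other markers too, but the other 21 measured had a median log2 fold change of 0.07, and 19 lay above −0.5. The GC and length correction left −3.25 for Cd163 and −2.22 for Pla2g7. An effect of the genotype on these genes within macrophages, and a change in the kind of macrophage, stay open and were not tested.

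PPARA target genes kept a median of −0.27 after the GC and length correction, and of −0.328 to −0.212 when any 1 library was left out (highest without GRMAC 3), which argues against either as the whole source. A lower share of hepatocyte RNA is argued against, since the hepatocyte score differed by 0.005, GRMAC minus GRflox (SD 0.027 in GRflox and 0.053 in GRMAC). The PPARA score minus the hepatocyte score differed by −0.343 (SD 0.190 and 0.236, exact permutation test, p = 0.0476). That value nearly repeats the difference of the PPARA score alone (−0.338), so its p is not separate evidence. The axis also varied within genotypes. With GRflox 4 and GRMAC 4 exchanged, edgeR called 29 genes, none of them among the 22, and 6 of the 29 were PPARA targets (Ehhadh, Plin2, Acot1, Acot2, Crat and Cidec). These 2 libraries lie against their genotype on the PPARA score, so the exchange lines the groups up on it, and the 6 genes restate that overlap. Cd163 places both libraries in their labelled genotype, and the reason for this variation between animals stays open.

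Other splits of the 10 libraries into 5 and 5 were fitted, 100 of the 126 possible. As many genes as the real 22 were called in 2 of the 100, the real one included. The highest of the others was the 29 just described. A number this high was rare among the splits, but another split gave more, so chance is not excluded for the number of genes. As many lists as the real 9 passed camera in 22 of the 100, with up to 13 in another split, so chance cannot be excluded for the number of lists. The other splits passed a median of 7 lists with this preset correlation, so its small p-values are weak evidence for single lists. At unadjusted p under 0.05 the real split had 2051 genes and the highest other 1743.

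Nfe2l1 drives proteasome genes, so subunit genes could fall with it. All 31 measured subunit genes had a negative log2 fold change (median −0.147), and 6 fell when adjusted over the list alone. An exact permutation test of the list score gave p = 0.00794, the smallest possible, and camera with the preset correlation gave p = 3.14e-11, or p = 2.8e-10 after the GC correction, where the median was −0.171. With an estimated correlation camera gave p = 0.119, which keeps open whether these genes fell beyond others. Rpl39 rose, but the 77 ribosomal protein genes had a median of 0.002, with quartiles of −0.04 and 0.05, which argues against a rise of the group. An exact permutation test of the ribosomal score gave p = 0.77, and camera gave p = 0.301, or p = 0.00412 after the GC correction, where the median was 0.022.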
